A study of Rattus norvegicus with 24 samples.

How the data were processed

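RNA of INS-1 cells was sequenced in 24 libraries, 4 for each combination of treatment (GLP-1, BMS-21 or Control) and time (1 h or 6 h). The library kit does not mark the strand, so reads from a transcript on the opposite strand count toward the gene they overlap, and reads shared by paralogs such as Ins1 and Ins2 cannot be assigned with certainty. Per the labels, reads were aligned to the rat genome build Rnor_5.0. The submitters' notes name TopHat2, Bowtie2, SAMtools, Subread, DESeq and DESeq2 without giving each tool's role, and the version of the gene annotation is not stated.

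The authors deposited 6 tables, 1 for each pair of groups at a time point, each with 26404 genes and 8 libraries, so that each library is in 2 tables. The values per library are the authors' normalised read counts (a signal on a linear scale), that is, counts divided by 1 size factor for each library within its table. The deposited tables also hold the authors' log2 fold change and the authors' adjusted p-value for the pair of groups. In every table the values of a library were whole multiples of 1 step (100% of values, within a tolerance of 0.001), which gave back the number of reads of each gene, and the reads of a library recovered from its 2 tables were the same for all genes. A symbol was present for 18465 identifiers and absent for 7939. In 143 cases the tables gave different symbols for an identifier, 25 of them in a table whose symbols had partly been turned into dates, and genes were therefore matched by identifier.

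The recovered totals were 10667350 to 13148970 reads per library. On simulated data with 200 changed genes, limma recovered 44.0 to 72.0% of genes changed 1.25-fold, 78.0 to 92.0% of those changed 1.5-fold and 90.0 to 100.0% of those changed 2-fold, and limma and edgeR made 2.02 to 11.4% false calls where 5% is nominal.

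The comparisons of 2 groups used limma 3.58.1 (trend and robust options) in R 4.3.3 on log2 of the normalised count plus 1, for genes with a mean of at least 10 over the 8 libraries, with Benjamini-Hochberg adjusted p under 0.05 as the threshold and no block. The fold is 2 to the power of the fitted log2 change. The 14 gene lists (299 genes, 279 matched) were tested with camera at its preset inter-gene correlation of 0.01, two-sided and adjusted over the 14 lists, and again with the correlation estimated from the residuals. For each list the members past the threshold were counted over all genes and adjusted over the list alone. The change of a response between 1 h and 6 h, and Control at 6 h against 1 h, were tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr) on the recovered reads, since the authors' size factors were set within each table. Both responses at a time share their controls, and their agreement was therefore compared with simulated unchanged groups and with the controls split.

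Named genes followed a rule with 3 parts. The first took up to 8 genes with the largest increase and up to 8 with the largest decrease past the threshold, with a mean of at least 50, an official symbol and no overlap between the groups. The second took up to 3 members with the smallest adjusted p in each list with a member past the threshold, and the third took Glp1r, Ins1, Ins2, Fos, Crem, Nr4a1, Per1, Irs2, Pde4b and Pdx1 in every comparison. A few list members that went against the rest of their list fall outside this rule and are named as chosen after their values were seen. A few genes that the rule selects are not reported here. The groups, tests, lists, this rule and the first set of alternatives were fixed before the data were examined.

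The replicate numbers were tested for pairing. After the group means were removed, libraries of the same number in the groups of a comparison correlated across genes by 0.119 to 0.406 over 24 pairs of libraries, so the numbers pair the samples, and fits with the replicate number as a block stand beside the unblocked ones where they change a call. On the first principal component of the same values (25.9% of the variance over 10799 genes) every library of replicates 1 and 2 (at most -3.88) was apart from every library of replicates 3 and 4 (at least 3.50), and the comparisons were therefore repeated within each of these pairs. No library was a duplicate of another, since the differences between libraries of a group exceeded counting error in all 36 pairs (chi-squared over its degrees of freedom 1.30 to 5.44).

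Alternatives fixed beforehand were pseudocounts of 0.5 and 5, a mean of at least 50 or no filter, TMM against median-of-ratios factors, DESeq2 1.42.0 on the recovered reads, all 24 libraries in 1 fit, the replicate block, a fold of at least 1.5, the estimated correlation and leaving out each library in turn. The edgeR test on the recovered reads, edgeR and DESeq2 with the block, scaling by library totals, the estimated correlation with the block and the tests within replicates 1 and 2 or 3 and 4 were chosen after seeing the data. No library was left out. Bias by GC content or gene length was not examined.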

Results

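INS-1 is a rat insulinoma line that secretes insulin and serves as a model of the pancreatic beta cell. Its transcripts were profiled after treatment with GLP-1 (glucagon-like peptide 1, a gut hormone whose receptor raises cAMP in beta cells) at 100 nM, with BMS-21, a compound given by code name only, at 1 µM, or with DMSO as the vehicle (Control). Cells were held for 90 min at 3 mM glucose, moved to 11 mM glucose together with the treatment, and collected after 1 h or 6 h. The 24 libraries form 6 groups of 4. They held 10667350 to 13148970 reads assigned to genes. Between 15899 and 16223 genes had at least 1 read in each, and the most abundant gene, COX1, took 1.93 to 2.21% of the reads. A transcript with 3 reads, taken as the floor of detection, corresponded to 0.228 to 0.281 RPM (reads scaled to the library total), and this floor covers counting error only. The labels do not state that the replicates were separate cultures, so the p-values measure only the spread between these samples. In what follows the value after ± is the standard error beside a log2 fold change and the standard deviation beside a mean normalised read count, with n = 4 libraries in each group.

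The comparison of GLP-1 with Control at 1 h asked which transcripts the hormone changed first. Immediate early transcription factors, which signalling induces without new protein synthesis, rose most. Fosb (ENSRNOG00000046667), which encodes a subunit of the transcription factor AP-1, rose 34.2-fold, from 26.4 ± 2.74 to 934 ± 35.1 normalised counts (log2 fold change 5.10 ± 0.09, adjusted p = 3.88e-24). The orphan nuclear receptor genes Nr4a1 (ENSRNOG00000007607), Nr4a2 and Nr4a3 rose with log2 fold changes of 4.32 ± 0.04, 4.24 ± 0.09 and 4.20 ± 0.13. The AP-1 genes Fosl2 (4.01 ± 0.07) and Fos (3.75 ± 0.08) rose as well. Fst, which encodes the activin antagonist follistatin (3.72 ± 0.16), was also among the 8 largest increases of genes eligible to be named. So was Sik1, a cAMP-induced kinase that restrains the coactivators of CREB (3.63 ± 0.06). The largest decreases were in Txnip (ENSRNOG00000021201), whose product binds thioredoxin and restrains glucose uptake (3.20-fold lower, from 13901 ± 679.6 to 4341 ± 198 normalised counts, log2 fold change -1.68 ± 0.04), and in Mycn, a transcription factor gene of the Myc family (-1.41 ± 0.13). Zfp189 (-1.15 ± 0.07), Bbs10 (-1.07 ± 0.11), and the adenosine receptor gene Adora2b (-1.05 ± 0.15) followed. Next came Phlda1 (from 437 ± 48.1 to 217 ± 20.1 normalised counts), Six4 (-0.97 ± 0.10) and Hes1, a repressor downstream of Notch (-0.95 ± 0.08).

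Among the immediate early transcription factors 18 of 23 rose and 3 fell, or 18 and 4 adjusted over the list alone (camera adjusted p = 2.28e-40), with a median log2 fold change of 1.89. The 3 that fell, Ier5 (-0.66 ± 0.10), Klf10 (-0.85 ± 0.04) and Zfp36 (-0.76 ± 0.08), were named after their values were seen. Of the targets of CREB and its CRTC coactivators, 14 of 23 rose and 0 fell, or 15 and 0 adjusted over the list alone (camera adjusted p = 1.96e-32). They included Gem, a small GTPase that limits calcium channels (2.10 ± 0.04), the clock gene Per1 (1.85 ± 0.04) and Crem, whose short products repress cAMP-driven transcription (2.08 ± 0.11). Irs2, an insulin receptor substrate, rose 2.14-fold (1.10 ± 0.03), and the cAMP phosphodiesterase gene Pde4b rose too (0.64 ± 0.17, adjusted p = 0.0160, 0.0664 to 0.0803 without Control 1h replicate 3 or 4 or GLP-1 1h replicate 1 or 2). In the list of MAPK phosphatases and Sprouty proteins, which damp MAPK signalling, 7 of 14 rose and 2 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 5.08e-07). Dusp1 (1.55 ± 0.05), Dusp10 (1.41 ± 0.07) and Dusp8 (0.40 ± 0.04) had the smallest p-values there. The 2 that fell, seen only afterwards, were Dusp14 (-0.48 ± 0.14) and Spry2 (-0.46 ± 0.08).

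Beta-cell genes were tested too. Of the list for beta-cell identity and glucose sensing 6 of 22 rose and 1 fell, or 6 and 1 adjusted over the list alone, with a median of 0.01 (camera adjusted p = 0.0363, 0.0587 to 0.204 without Control 1h replicate 4 or GLP-1 1h replicate 2 or 3, but adjusted p = 0.370 with an estimated correlation). The insulin gene activators Mafa (0.85 ± 0.06) and Pdx1 (0.24 ± 0.05) and the identity factor Nkx2-2 (0.62 ± 0.05) rose, and Neurod1 fell (-0.53 ± 0.05). The values of Glp1r, the receptor of GLP-1 (-0.04 ± 0.04, adjusted p = 0.787), Ins1 (0.03 ± 0.03, adjusted p = 0.711) and Ins2 (-0.05 ± 0.10, adjusted p = 0.897) did not pass the test. Ins1 and Ins2 are closely related paralogs between which reads can be miscounted, so their levels are uncertain here and in every later comparison. Of the secretory granule and exocytosis genes 4 of 21 rose and 0 fell, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.00382, but 0.105 with the block and an estimated correlation), among them Scg2 (0.22 ± 0.03), Syt4 (0.46 ± 0.06) and Syt7 (0.17 ± 0.04). In cholesterol and fatty acid synthesis 7 of 21 rose and 1 fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.000778, but 0.105 with both). Insig1 (0.54 ± 0.04) and the sterol carrier gene Stard4 (1.53 ± 0.09) rose. The 1 that fell was Fasn (-0.11 ± 0.03), named after its value was seen. Glycolysis and glucose uptake had 3 of 14 members higher and 0 lower, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.0412, 0.0583 to 0.219 without Control 1h replicate 3 or 4 or GLP-1 1h replicate 1 or 2, but adjusted p = 0.466 with an estimated correlation). Its members past the threshold were Aldoa (0.22 ± 0.04), Pgam1 (0.11 ± 0.03, adjusted p 0.0726 to 0.131 without Control 1h replicate 1, 2 or 3 or GLP-1 1h replicate 1, 3 or 4) and Pfkfb3 (0.58 ± 0.13, adjusted p 0.0933 to 0.110 without Control 1h replicate 4 or GLP-1 1h replicate 1, 2 or 4).

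The list of the unfolded protein response and integrated stress response held a single gene that rose, Ppp1r15a (0.57 ± 0.11, adjusted p 0.0566 to 0.0589 without GLP-1 1h replicate 1 or 4). Here 1 of 20 rose and 0 fell, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.0363, 0.0910 to 0.282 without Control 1h replicate 1 or 2 or GLP-1 1h replicate 3 or 4, but adjusted p = 0.644 with an estimated correlation). For apoptosis and survival 2 of 12 rose and 3 fell, or 2 and 4 adjusted over the list alone, and the list as a whole was lower (camera adjusted p = 0.0363, 0.0552 to 0.0910 without Control 1h replicate 3 or GLP-1 1h replicate 4, but adjusted p = 0.370 with an estimated correlation). Besides Txnip, the gene of the death-promoting protein PUMA, Bbc3, fell (-0.48 ± 0.08), while that of BIM, Bcl2l11, rose (0.55 ± 0.11). Of the cell cycle genes 4 of 25 rose and 0 fell, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.349). The cyclin D1 gene Ccnd1 (1.43 ± 0.12), the inhibitor gene Cdkn1b (0.44 ± 0.04) and Pcna (0.16 ± 0.04) rose. The median of that list lay below 0 and its mean above. The clock list gave 1 of 13 members higher and 2 lower, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.261). Cry2 was higher (1.78 ± 0.09) and Nr1d1 (-0.86 ± 0.09) and Bhlhe40 (-0.79 ± 0.04) were lower. In insulin and IGF signalling 2 of 18 rose and 1 fell, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.776). Pik3r1 (0.54 ± 0.05) and Irs1 (0.47 ± 0.10) were higher and Foxo1 (-0.37 ± 0.05) was lower. For adenylyl cyclase, PKA, EPAC and receptor desensitisation 0 of 23 rose and 1 fell, or 0 and 1 adjusted over the list alone (camera adjusted p = 0.844). The latter was the PKA subunit gene Prkacb (-0.15 ± 0.04, adjusted p 0.0551 to 0.0638 without Control 1h replicate 2 or GLP-1 1h replicate 4). Among markers of other islet, exocrine, duct and stromal cells, of which 4 were measured, 1 of 4 rose and 1 fell, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.776). Sox9 was higher (1.09 ± 0.26, adjusted p 0.0540 to 0.0743 without Control 1h replicate 4 or GLP-1 1h replicate 1).

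In total 530 genes were higher and 307 lower with GLP-1 at 1 h, of 12715 tested with limma, and 103 and 13 of them changed at least 2-fold. With the replicate number as a block the counts were 857 and 656, and 835 of the 837 genes were among them. Tested alone, replicates 1 and 2 gave 905 genes and replicates 3 and 4 gave 556, and all 837 had the same direction in both pairs. With 2 libraries per group, Crem (1.90, against 2.26 in replicates 1 and 2), Pcna (0.14, 0.17), Pgam1 (0.11, 0.11), Prkacb (-0.16, -0.13) and Sox9 (0.87, 1.30) did not pass in replicates 3 and 4 alone. Scaling by library totals, which moved the median of all genes by -0.03, gave 449 higher and 506 lower genes and ended the calls of Pgam1 and of the lists for beta-cell identity, stress response, apoptosis and glycolysis.

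**Figure D1:**
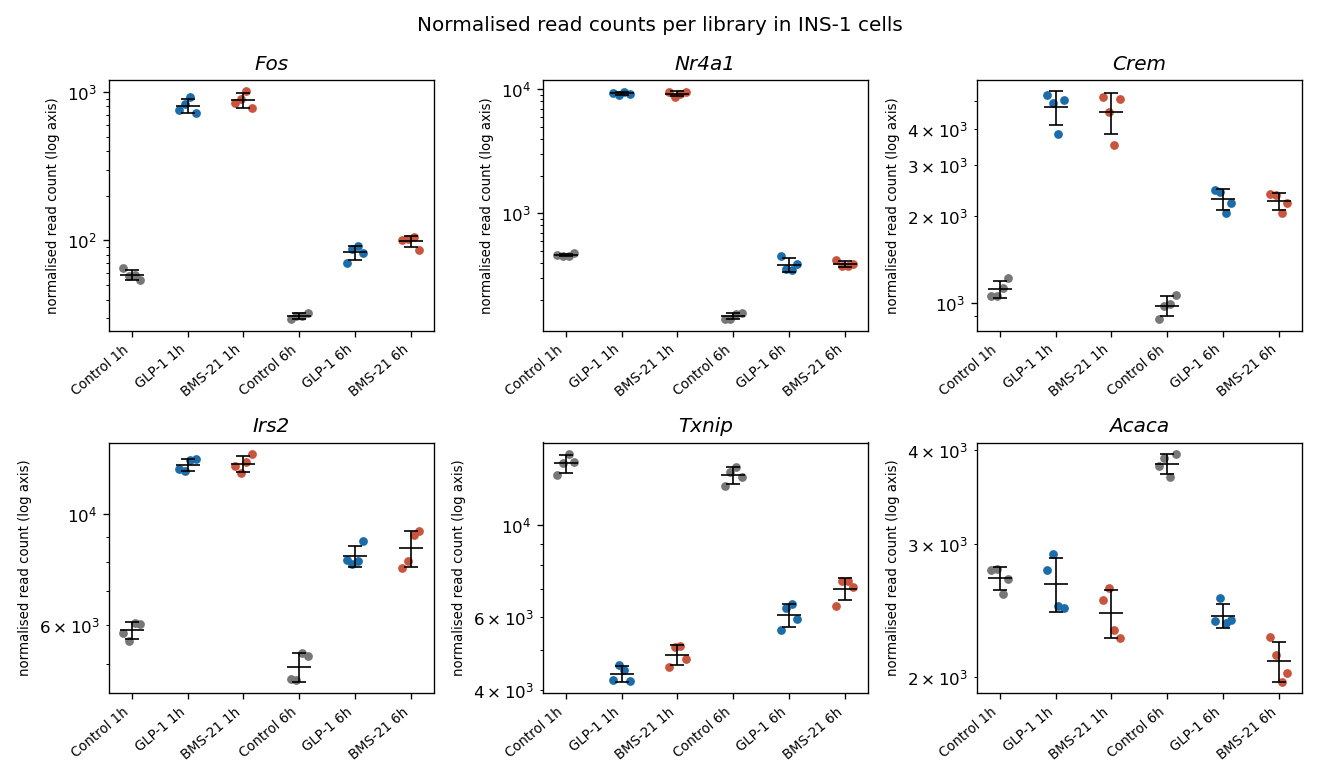
Normalised read counts of Fos, Nr4a1, Crem, Irs2, Txnip and Acaca in the 6 groups, on log axes, with 1 point per library and bars for the mean ± SD of 4 libraries. Nr4a1 averaged 462 ± 10.5 in Control, 9291 ± 238 with GLP-1 and 9224 ± 417 with BMS-21 at 1 h.

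The comparison of GLP-1 with Control at 6 h asked what the response had become by then. The largest increases were in Asb4 (ENSRNOG00000009197), a substrate adaptor of ubiquitin ligases, which rose 10.6-fold, from 19.2 ± 5.70 to 208 ± 30.4 normalised counts (log2 fold change 3.40 ± 0.17, adjusted p = 1.07e-11), and in Rxfp3, which encodes a relaxin-family peptide receptor (3.12 ± 0.13). Sv2c, a synaptic vesicle protein gene (2.73 ± 0.08), Ccnd1 (5.87-fold, 2.55 ± 0.09) and the calcium-dependent kinase gene Camk4 (2.21 ± 0.05) followed. Mylk (2.17 ± 0.04), the secreted stanniocalcin gene Stc1 (2.14 ± 0.05) and the oxytocin receptor gene Oxtr (1.98 ± 0.11) came next. The largest decreases were in Lrrc39 (2.90-fold lower, -1.53 ± 0.09), Prex2 (-1.53 ± 0.11), Mycn (-1.43 ± 0.12), and the monoglyceride lipase gene Mgll (-1.38 ± 0.13). Rgs22 (-1.38 ± 0.08), Gas7 (-1.37 ± 0.10), Adora2b (-1.33 ± 0.08) and Dpysl3 (-1.27 ± 0.14) were the others.

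Targets of CREB were mostly above Control at 6 h, where 15 of 22 rose and 1 fell, or 16 and 1 adjusted over the list alone (camera adjusted p = 5.83e-13). Stc1, the phosphodiesterase gene Pde10a (1.28 ± 0.04) and Vgf, a granule peptide gene (0.96 ± 0.04), had the smallest p-values. Crem (1.22 ± 0.06), Irs2 (0.74 ± 0.04), Pde4b (1.13 ± 0.12) and Per1 (0.31 ± 0.05) were also higher. The 1 that fell, named after its value was seen, was Pde3b (-0.23 ± 0.03). The MAPK phosphatase and Sprouty list had 10 of 14 members higher and 0 lower, or 12 and 0 adjusted over the list alone (camera adjusted p = 3.09e-08). Spry1 (1.66 ± 0.10), Spry4 (1.16 ± 0.08) and Dusp4 (1.19 ± 0.08) led it. Of the immediate early factors 12 of 22 rose and 3 fell, or 13 and 3 adjusted over the list alone (camera adjusted p = 0.000435, but adjusted p = 0.196 with an estimated correlation). Among them were Nr4a1 at 1.36 ± 0.08, Fos at 1.39 ± 0.13, Fosl2 at 1.49 ± 0.11 and Klf4 at 1.74 ± 0.13. The 3 lower ones, seen afterwards, were Klf10 (-0.47 ± 0.06), Zfp36 (-0.60 ± 0.08) and Arc (-0.53 ± 0.08).

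In the granule and exocytosis list 11 of 21 rose and 1 fell, or 13 and 1 adjusted over the list alone (camera adjusted p = 5.68e-06). The granule genes Scg2 (0.64 ± 0.03) and Ptprn (0.71 ± 0.04) and the fusion protein gene Snap25 (0.62 ± 0.05) rose. Syt13 fell (-0.23 ± 0.05, named after its value was seen). In the unfolded protein and integrated stress response 14 of 20 rose and 1 fell, or 15 and 1 adjusted over the list alone (camera adjusted p = 2.61e-09, but adjusted p = 0.205 with an estimated correlation). Xbp1 (0.45 ± 0.04), Pdia6 (0.34 ± 0.04) and Calr (0.34 ± 0.04) were higher. The 1 lower member, chosen after the fact, was the oxidase gene Ero1b (-0.28 ± 0.07). For beta-cell identity and glucose sensing 12 of 22 rose and 5 fell, or 12 and 5 adjusted over the list alone (camera adjusted p = 0.0486, 0.0563 to 0.0939 without Control 6h replicate 3 or 4 or GLP-1 6h replicate 1, 2 or 4, but adjusted p = 0.205 with an estimated correlation). Ins1 (0.25 ± 0.03), Glp1r (0.28 ± 0.04), the receptor gene Gipr (0.34 ± 0.03), Isl1 (0.53 ± 0.05) and Pdx1 (0.16 ± 0.05, adjusted p = 0.0115, 0.0518 to 0.0528 without Control 6h replicate 4 or GLP-1 6h replicate 1) rose. The glucose transporter gene Slc2a2 fell (-0.67 ± 0.03), and Ins2 did not pass (-0.06 ± 0.04, adjusted p = 0.221). Glycolysis and glucose uptake had 6 of 14 members higher and 2 lower, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0274, but adjusted p = 0.205 with an estimated correlation). Aldoa (0.59 ± 0.04), Pfkp (0.57 ± 0.05) and Pgam1 (0.30 ± 0.03) were higher.

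Genes of cholesterol and fatty acid synthesis, of which 19 of 21 rose over time in Control, were below Control at 6 h. Against it 1 of 21 rose and 17 fell, or 1 and 17 adjusted over the list alone (camera adjusted p = 4.69e-08, median -0.24). The acetyl-CoA carboxylase gene Acaca (-0.67 ± 0.04), the squalene synthase gene Fdft1 (-0.61 ± 0.06) and Acly (-0.29 ± 0.03) fell. Stard4 rose (0.50 ± 0.05, named after its value was seen). All 13 clock genes measured changed, since 5 of 13 rose and 8 fell, or 5 and 8 adjusted over the list alone (camera adjusted p = 0.0308, but adjusted p = 0.201 with an estimated correlation). Tef (-0.57 ± 0.04), Bhlhe40 (-0.60 ± 0.05) and Nr1d2 (-0.50 ± 0.05) were lower. For the cell cycle 2 of 25 rose and 8 fell, or 2 and 9 adjusted over the list alone (camera adjusted p = 0.0983, 0.0326 without GLP-1 6h replicate 2). Ccnd1 and Ccnd3 (0.77 ± 0.05) were higher and Ccnd2 was lower (-0.35 ± 0.03). The list's median (-0.07) and test were negative while its mean (0.05) was positive. Apoptosis and survival had 0 of 12 members higher and 3 lower, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.154). Txnip (-1.11 ± 0.04), Bcl2l1 (-0.24 ± 0.04) and Bbc3 (-0.52 ± 0.11) were lower. In insulin and IGF signalling 3 of 18 rose and 4 fell, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.807). The receptor gene Igf1r was 3.87-fold higher (1.95 ± 0.05), Pik3r1 was higher (0.32 ± 0.05) and Igfbp3 was lower (-0.40 ± 0.04). Of the adenylyl cyclase and PKA list 6 of 23 rose and 5 fell, or 6 and 6 adjusted over the list alone (camera adjusted p = 0.807). Pde1c was higher (1.27 ± 0.06) and Adcy1 (-0.90 ± 0.07) and Prkacb (-0.43 ± 0.04) were lower. In both of these lists the median and the test were negative and the mean positive. The 4 markers of other cells gave 0 of 4 members higher and 1 lower, or 0 and 1 adjusted over the list alone (camera adjusted p = 0.725). The median was positive beside a negative mean and test.

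With GLP-1 at 6 h 2044 genes were higher and 1967 lower of 12641 tested with limma, 138 and 54 of them by at least 2-fold. The block gave 5331, replicates 1 and 2 alone 3870 and 3 and 4 alone 3334. All 4011 had the same direction in both pairs. Scaling by library totals (median of all genes -0.05) gave 1451 higher and 2960 lower genes. It ended the calls of Pdx1 and of the clock list and brought Ins2 past the threshold as lower.

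The comparison of BMS-21 with Control at 1 h asked the same of the compound. Immediate early factors again rose most, led by Fosb (34.9-fold, from 26.0 ± 2.69 to 940.1 ± 77.2 normalised counts, log2 fold change 5.12 ± 0.09, adjusted p = 9.44e-22). Nr4a1 (4.31 ± 0.04), Nr4a2 (4.31 ± 0.10), Nr4a3 (4.07 ± 0.19), and Fosl2 (3.94 ± 0.10) followed. Fos (3.87 ± 0.08), Sik1 (3.66 ± 0.06) and Rgs2, which encodes a regulator that shortens G-protein signalling (3.60 ± 0.08), made up the rest of the 8 largest increases. The largest decreases were in Mycn (-1.54 ± 0.13), Txnip (2.89-fold lower, -1.53 ± 0.04), Zfp189 (-1.30 ± 0.08), Adora2b (-1.22 ± 0.16), Phlda1 (-1.07 ± 0.09) and the Kruppel-like factor gene Klf2 (-0.98 ± 0.17). With them were Klf6 (from 235 ± 48.1 to 117 ± 29.3 normalised counts) and Fam46c (from 321 ± 12.5 to 161 ± 11.1).

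Of the immediate early factors 18 of 23 rose and 3 fell, or 18 and 4 adjusted over the list alone (camera adjusted p = 7.08e-39), with Junb at 2.63 ± 0.04. The 3 lower ones, named after their values were seen, were Ier5 (-0.85 ± 0.11), Klf10 (-0.88 ± 0.04) and Zfp36 (-0.84 ± 0.08). CREB targets showed 13 of 23 members higher and 0 lower, or 13 and 0 adjusted over the list alone (camera adjusted p = 7.91e-29). Per1 (1.81 ± 0.05), Crem (2.02 ± 0.13) and Irs2 (2.15-fold, 1.11 ± 0.03) rose, while Pde4b did not pass (0.27 ± 0.17, adjusted p = 0.523). In the MAPK phosphatase and Sprouty list 7 of 14 rose and 1 fell, or 7 and 3 adjusted over the list alone (camera adjusted p = 5.52e-05, but adjusted p = 0.0744 with an estimated correlation). Dusp1 (1.62 ± 0.05), Dusp10 (1.29 ± 0.07) and Spry1 (0.84 ± 0.09) were higher and Spry2 (-0.62 ± 0.10, seen afterwards) was lower. For beta-cell identity and glucose sensing 6 of 22 rose and 1 fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.00765, 0.0646 without Control 1h replicate 4, but adjusted p = 0.360 with an estimated correlation). Mafa (0.79 ± 0.05), Nkx2-2 (0.62 ± 0.05), Pax6 (0.32 ± 0.04), Pdx1 (0.25 ± 0.05) and, narrowly, Ins1 (0.10 ± 0.03, adjusted p = 0.0321, 0.0548 to 0.150 without Control 1h replicate 1, 2 or 4 or BMS-21 1h replicate 1, 2 or 4) were higher. The lower one, named after its value was seen, was Neurod1 (-0.56 ± 0.07). Glp1r (-0.04 ± 0.04, adjusted p = 0.723) and Ins2 (0.01 ± 0.07, adjusted p = 0.967) did not pass the test.

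The granule and exocytosis list had 2 of 21 members higher and 0 lower, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.00347, but adjusted p = 0.0956 with an estimated correlation). Those were Scg2 (0.28 ± 0.03) and Syt4 (0.47 ± 0.07). The stress response list had 1 of 20 members higher and 0 lower, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.00347, 0.156 without BMS-21 1h replicate 3, but adjusted p = 0.577 with an estimated correlation). The first of these was Ppp1r15a (0.63 ± 0.11, adjusted p 0.0546 to 0.0639 without BMS-21 1h replicate 1 or 4). In cholesterol and fatty acid synthesis 7 of 21 rose and 2 fell, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.444). Insig1 (0.47 ± 0.04) and Stard4 (1.38 ± 0.12) were higher. Named after their values were seen, Fasn (-0.14 ± 0.03) and Acaca (-0.16 ± 0.05) were lower. The median of that list (-0.04) was negative, its mean (0.07) and test positive. Apoptosis and survival had 1 of 12 members higher and 3 lower, or 1 and 3 adjusted over the list alone (camera adjusted p = 0.0516, 0.0322 to 0.0469 without Control 1h replicate 2 or BMS-21 1h replicate 1, 2 or 3, and 0.00591 with the replicate block, but adjusted p = 0.224 with an estimated correlation). Txnip and Bbc3 (-0.55 ± 0.08) were lower. For the cell cycle 4 of 25 rose and 1 fell, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.654). Ccnd1 (1.39 ± 0.11), Cdkn1b (0.34 ± 0.04) and Pcna (0.13 ± 0.04, adjusted p 0.0781 to 0.147 without Control 1h replicate 1 or 3 or BMS-21 1h replicate 1) were higher. That list had a negative median beside a positive mean and test. The clock list gave 1 of 13 members higher and 2 lower, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.419), with a positive mean beside a negative median and test. The changed members were Cry2 (1.76 ± 0.13), Bhlhe40 (-0.78 ± 0.04) and Nr1d1 (-0.84 ± 0.11). In insulin and IGF signalling 1 of 18 rose and 1 fell, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.463). Pik3r1 was higher (0.41 ± 0.07) and Foxo1 was lower (-0.29 ± 0.05). Of adenylyl cyclase and PKA genes 0 of 23 rose and 1 fell, or 0 and 1 adjusted over the list alone (camera adjusted p = 0.798). The latter was Prkacb (-0.14 ± 0.04, adjusted p 0.0610 to 0.0974 without Control 1h replicate 1 or 2 or BMS-21 1h replicate 1, 3 or 4), and the test was negative beside a positive median and mean. Other-cell markers gave 1 of 4 members higher and 1 lower, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.463). Sox9 was higher (0.89 ± 0.22, adjusted p 0.0587 to 0.0596 without Control 1h replicate 2 or 4). In glycolysis and glucose uptake 0 of 14 rose and 0 fell, or 0 and 0 adjusted over the list alone by limma (camera adjusted p = 0.199, 0.0249 to 0.0491 without Control 1h replicate 1 or BMS-21 1h replicate 4).

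With BMS-21 at 1 h 450 genes were higher and 301 lower of 12697 tested with limma, 99 and 17 of them by at least 2-fold. The replicate block gave 851 and 700, with 749 of the 751 genes among them. Replicates 1 and 2 alone gave 828 genes, replicates 3 and 4 alone 495, and all 751 had the same direction in both pairs. Of the named genes, Crem (1.84, against 2.19 in replicates 1 and 2), Foxo1 (-0.16, -0.41), Ins1 (0.08, 0.11), Nr4a3 (3.88, 4.26), Pcna (0.12, 0.14), Prkacb (-0.15, -0.13) and Sox9 (0.72, 1.06) did not pass in replicates 3 and 4 alone. Scaling by library totals (median of all genes -0.03) gave 380 higher and 445 lower genes and ended the calls of Pcna and Ins1.

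**Figure D2:**
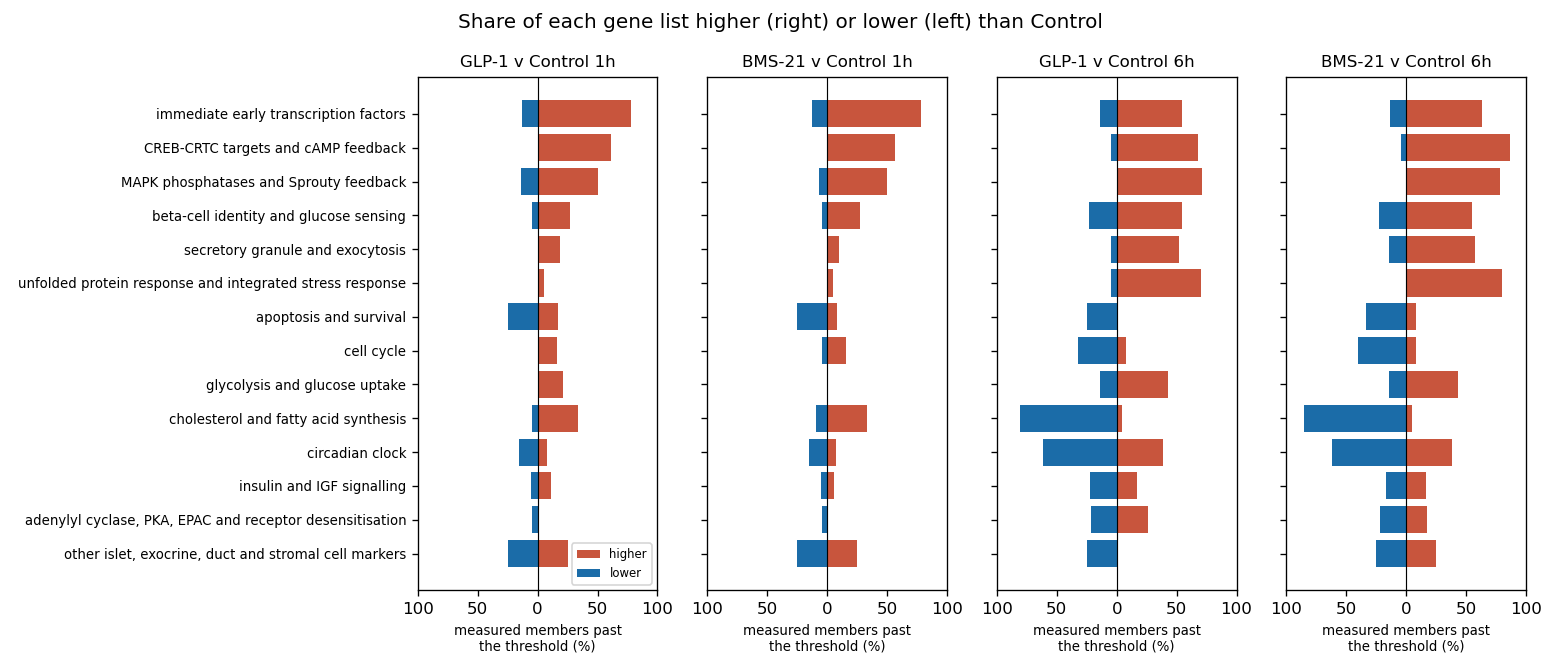
Share of the measured members of each of the 14 gene lists that passed the threshold as higher (red, to the right) or lower (blue, to the left), in percent, for GLP-1 and BMS-21 against Control at 1 h and 6 h. In cholesterol and fatty acid synthesis 7 of 21 members were higher with either agent at 1 h, and 17 (GLP-1) and 18 (BMS-21) of 21 were lower at 6 h.

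The comparison of BMS-21 with Control at 6 h asked what the compound had changed by then. Asb4 rose 12.9-fold, from 19.6 ± 5.82 to 257 ± 20.6 normalised counts (log2 fold change 3.69 ± 0.16, adjusted p = 6.66e-13). Rxfp3 (3.21 ± 0.12), Sv2c (2.87 ± 0.08), Ccnd1 (2.61 ± 0.10), and Camk4 (2.45 ± 0.05) followed. Mylk (2.31 ± 0.04), Igf1r (4.74-fold, 2.25 ± 0.08) and Stc1 (2.21 ± 0.04) completed the 8 largest increases. The largest decreases were in Lrrc39 (3.20-fold lower, -1.68 ± 0.09), Gas7 (-1.62 ± 0.12), the secreted protease gene Adamts8 (-1.57 ± 0.24), and the transglutaminase gene Tgm2 (-1.57 ± 0.25). Rgs22 (-1.56 ± 0.11), Cttnbp2 (-1.56 ± 0.12), Mycn (-1.53 ± 0.14) and Prex2 (-1.52 ± 0.11) were the others.

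Of the CREB targets 19 of 22 rose and 1 fell, or 19 and 1 adjusted over the list alone (camera adjusted p = 4.96e-13). Pde10a (1.47 ± 0.04), Vgf (0.91 ± 0.04), Crem (1.20 ± 0.06), Irs2 (0.79 ± 0.06), Pde4b (1.06 ± 0.12) and Per1 (0.20 ± 0.06) were among them, and Pde3b fell (-0.28 ± 0.04, named after its value was seen). The MAPK phosphatase and Sprouty list had 11 of 14 members higher and 0 lower, or 11 and 0 adjusted over the list alone (camera adjusted p = 1.30e-08). Spry1 (1.88 ± 0.11), Dusp4 (1.28 ± 0.08) and Dusp6 (1.36 ± 0.10) were higher. Immediate early factors gave 14 of 22 members higher and 3 lower, or 15 and 3 adjusted over the list alone (camera adjusted p = 8.78e-05, but adjusted p = 0.103 with an estimated correlation). Klf4 (2.03 ± 0.13), Fos (1.63 ± 0.13), Nr4a2 (1.40 ± 0.10) and Nr4a1 (1.38 ± 0.07) were higher. Seen afterwards, Klf10 (-0.37 ± 0.05), Zfp36 (-0.42 ± 0.09) and Arc (-0.58 ± 0.07) were lower. In the granule and exocytosis list 12 of 21 rose and 3 fell, or 13 and 3 adjusted over the list alone (camera adjusted p = 8.78e-05, adjusted p = 0.0499 with an estimated correlation, but 0.132 with the block as well). Scg2 (0.78 ± 0.03), Ptprn (0.75 ± 0.03) and Snap25 (0.63 ± 0.04) were higher. Again seen afterwards, Scg5 (-0.14 ± 0.05), Syt13 (-0.27 ± 0.05) and Cplx2 (-0.14 ± 0.05) were lower. The stress response list had 16 of 20 members higher and 0 lower, or 19 and 1 adjusted over the list alone (camera adjusted p = 5.46e-11, but adjusted p = 0.184 with an estimated correlation). Xbp1 (0.47 ± 0.04), Atf4 (0.45 ± 0.04) and Ppp1r15a (0.57 ± 0.06) were higher.

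For beta-cell identity and glucose sensing 12 of 22 rose and 5 fell, or 13 and 5 adjusted over the list alone (camera adjusted p = 0.0198, but adjusted p = 0.240 with an estimated correlation). Ins1 (0.29 ± 0.04), Glp1r (0.22 ± 0.04), Gipr (0.36 ± 0.03), Isl1 (0.58 ± 0.05) and Pdx1 (0.13 ± 0.04, adjusted p = 0.0298, 0.0513 to 0.128 without Control 6h replicate 2 or 4 or BMS-21 6h replicate 1 or 4) rose and Slc2a2 fell (-0.68 ± 0.03), while Ins2 did not pass (0.09 ± 0.15, adjusted p = 0.719). Within replicates 1 and 2 alone Ins2 was lower (-0.15, adjusted p = 7.29e-05), whereas replicates 3 and 4 gave 0.32 (adjusted p = 0.289). In cholesterol and fatty acid synthesis 1 of 21 rose and 18 fell, or 1 and 18 adjusted over the list alone (camera adjusted p = 1.70e-10, median -0.34). Hmgcs1 (-0.90 ± 0.06), Acaca (-0.87 ± 0.04) and Fdft1 (-0.71 ± 0.05) were lower and Stard4 (0.46 ± 0.05, named after its value was seen) was higher. The cell cycle list had 2 of 25 members higher and 10 lower, or 2 and 10 adjusted over the list alone (camera adjusted p = 0.0181, 0.0738 without BMS-21 6h replicate 3, but adjusted p = 0.292 with an estimated correlation). Ccnd1 and Ccnd3 (0.88 ± 0.05) were higher and Ccnd2 was lower (-0.49 ± 0.04). Its median (-0.14) and test were negative while its mean (0.01) was positive. For glycolysis and glucose uptake 6 of 14 rose and 2 fell, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0126, but adjusted p = 0.190 with an estimated correlation). Aldoa (0.70 ± 0.04), Pfkp (0.70 ± 0.05) and Pgam1 (0.33 ± 0.03) were higher. The clock list gave 5 of 13 members higher and 8 lower, or 5 and 8 adjusted over the list alone (camera adjusted p = 0.0584, 0.0427 to 0.0487 without Control 6h replicate 4 or BMS-21 6h replicate 2 or 3). Tef (-0.47 ± 0.05), Nr1d2 (-0.47 ± 0.05) and Bhlhe40 (-0.44 ± 0.05) were lower. Apoptosis and survival had 1 of 12 members higher and 4 lower, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.126). Txnip (-0.91 ± 0.04), Bbc3 (-0.74 ± 0.10) and Bcl2l1 (-0.24 ± 0.04) were lower. In insulin and IGF signalling 3 of 18 rose and 3 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.893). Pik3r1 (0.45 ± 0.05) was higher and Igfbp3 (-0.42 ± 0.05) was lower. Of adenylyl cyclase and PKA genes 4 of 23 rose and 5 fell, or 4 and 5 adjusted over the list alone (camera adjusted p = 0.893). Pde1c was higher (1.23 ± 0.07), Adcy1 (-1.06 ± 0.08) and Prkacb (-0.51 ± 0.04) were lower. The mean was positive there, the median and test negative. Other-cell markers gave 1 of 4 members higher and 1 lower, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.893). Gcg, which encodes proglucagon, was higher (0.39 ± 0.13, adjusted p 0.0645 to 0.0892 without Control 6h replicate 3 or 4 or BMS-21 6h replicate 1 or 2). The list had a positive median beside a negative mean and test.

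With BMS-21 at 6 h 2125 genes were higher and 2128 lower of 12640 tested with limma, 150 and 87 of them by at least 2-fold. The block gave 5008, replicates 1 and 2 alone 3850 and 3 and 4 alone 4147. In both pairs 4252 of the 4253 had the same direction. Gcg (0.29, against 0.50 in replicates 1 and 2) and Per1 (0.15, 0.25) did not pass in replicates 3 and 4 alone, nor Pdx1 in replicates 1 and 2 alone (0.10, 0.16). Scaling by library totals (median of all genes -0.06) gave 1510 higher and 3068 lower genes and ended the calls of Per1 and Pdx1.

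The direct comparison of BMS-21 with GLP-1 asked where the agents differed, at doses that were not matched (1 µM and 100 nM). At 1 h the log2 difference between BMS-21 and GLP-1 had 95% intervals of -0.08 to 0.06 for Nr4a1, -0.06 to 0.07 for Irs2, and -0.14 to 0.06 for Per1. They were -0.08 to 0.33 for Fos, -0.45 to 0.33 for Crem, -0.09 to 0.08 for Glp1r and -0.06 to 0.08 for Pdx1. Cholesterol and fatty acid synthesis genes were lower as a set with BMS-21 (median -0.07, camera adjusted p = 1.08e-07, and adjusted p = 0.0102 with an estimated correlation, or 0.0618 with the block as well). So were the MAPK phosphatases and Sprouty genes (median -0.11, camera adjusted p = 0.00405, but adjusted p = 0.105 with an estimated correlation). No single member of these lists passed in either direction, neither over all genes nor adjusted over the list alone. The interval of Pde4b, -0.68 to -0.06, excluded 0 before correction, but its adjusted p = 1.00. Those of Ins1 and Ins2 were 0.01 to 0.12 and -0.07 to 0.20.

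None of 12672 genes passed limma's threshold at 1 h, with 432 at an unadjusted p under 0.05, and edgeR, DESeq2 and the authors' deposited table gave 0 as well. With the replicate block DESeq2 gave 2 genes, and limma gave 28 higher and 57 lower genes, among them Ins1 (0.07, adjusted p = 1.95e-05) and Ins2 (0.07, adjusted p = 0.0117). Replicates 1 and 2 or 3 and 4 alone gave 0 genes by limma. The block also brought past the threshold the CREB (adjusted p 0.233 to 0.0264), beta-cell (0.520 to 0.0174), stress response (0.174 to 0.00444) and glycolysis (0.520 to 0.0219) lists. Each of these had adjusted p = 0.759 with an estimated correlation, and 0.342 to 0.447 with the block as well. Leaving out single libraries also brought in the CREB (0.0109 to 0.0286 without GLP-1 1h replicate 3 or BMS-21 1h replicate 1), stress response (1.81e-05 to 0.0411 without GLP-1 1h replicate 3 or 4 or BMS-21 1h replicate 1 or 2), glycolysis (0.0153 without BMS-21 1h replicate 1) and other-cell (0.0464 without GLP-1 1h replicate 3) lists. The camera adjusted p of the lists not past the threshold were 0.663 for immediate early factors, 0.663 for granule genes, and 0.663 for apoptosis. They were 0.287 for the cell cycle, 0.667 for the clock, 0.663 for insulin and IGF signalling, 0.663 for adenylyl cyclase and PKA and 0.450 for other-cell markers. Adjusted over the list alone, 2 immediate early factors were higher and 1 lower, and 1 apoptosis gene was higher. Median, mean and test differed in sign in the immediate early, apoptosis and adenylyl cyclase lists.

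At 6 h the genes that differed between the agents were Ccny (ENSRNOG00000018123), which encodes cyclin Y, higher with BMS-21 (from 1476 ± 43.5 to 1743 ± 25.6 normalised counts, log2 0.24 ± 0.04, adjusted p = 0.0380), and Hspa12a (ENSRNOG00000018019), of the Hsp70 family, lower (from 682 ± 24.9 to 539 ± 35.0, log2 -0.34 ± 0.06, adjusted p = 0.0380). Leaving out any 1 of the 8 libraries ended both calls, with adjusted p from 0.0613 to 0.218 for Ccny and from 0.0613 to 0.353 for Hspa12a. The 95% interval of the difference was -0.14 to 0.18 for Nr4a1, 0.01 to 0.48 for Fos, -0.15 to 0.11 for Crem, and -0.06 to 0.17 for Irs2. It was -0.23 to 0.01 for Per1, -0.28 to 0.14 for Pde4b, -0.11 to 0.06 for Pdx1, -0.14 to 0.03 for Glp1r, -0.05 to 0.15 for Ins1 and -0.22 to 0.53 for Ins2, with adjusted p from 0.772 (Fos) to 0.984 (Nr4a1). As sets, the stress response genes were higher with BMS-21 (median 0.10, camera adjusted p = 0.000196) and cholesterol and fatty acid synthesis was lower (median -0.08, camera adjusted p = 1.70e-08). The immediate early (camera adjusted p = 0.0260), MAPK phosphatase (camera adjusted p = 0.0441) and glycolysis (camera adjusted p = 0.0224) lists were also higher and the cell cycle list lower (camera adjusted p = 0.0224). All 6 calls were lost, with adjusted p = 0.317 with an estimated correlation for cholesterol and fatty acid synthesis and adjusted p = 0.379 with an estimated correlation for the others. With the block all 6 passed at the preset correlation (1.24e-15 to 0.0461) and 0 of 6 by camera at an estimated one (0.0852 to 0.277). The adjusted p with the preset correlation also missed the threshold when some single libraries were left out: 0.0705 to 0.196 without GLP-1 6h replicate 1 or 2 or BMS-21 6h replicate 3 or 4 for immediate early factors, and 0.0510 to 0.295 without GLP-1 6h replicate 1, 2 or 4 or BMS-21 6h replicate 3 or 4 for MAPK phosphatases. It was 0.0510 to 0.196 without GLP-1 6h replicate 2 or BMS-21 6h replicate 3 for the stress response, 0.184 to 0.516 without GLP-1 6h replicate 2 or BMS-21 6h replicate 3 for the cell cycle and 0.145 to 0.196 without GLP-1 6h replicate 4 or BMS-21 6h replicate 3 for glycolysis.

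Of 12629 genes 1 was higher and 1 lower with BMS-21 at 6 h by limma, with 800 at an unadjusted p under 0.05. The count was 2 by edgeR, 18 by DESeq2 and 9 higher and 10 lower in the authors' deposited table. With the replicate block 97 were higher and 120 lower by limma, both named genes among them, and DESeq2 gave 38 genes. On their own, replicates 1 and 2 gave 37 genes and replicates 3 and 4 gave 39, with both named genes in the same direction in each pair. Over all genes 0 list members passed limma's threshold, and adjusted over the list alone 1 CREB, 1 granule, 1 apoptosis and 1 insulin and IGF gene were higher and 1 cell cycle and 2 cholesterol genes lower. The camera adjusted p of the lists not past the threshold were 0.283 for CREB targets, 0.129 for beta-cell genes (0.0461 with the block, 0.0244 without BMS-21 6h replicate 1, but adjusted p = 0.379 with an estimated correlation), 0.379 for granule genes and 0.900 for apoptosis. They were 0.162 for the clock, 0.139 for insulin and IGF signalling, 0.850 for adenylyl cyclase and PKA and 0.345 for other-cell markers. Median, mean and test differed in sign in the CREB, apoptosis and adenylyl cyclase lists.

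The responses to the agents were then set side by side, as in the plot of BMS-21 against GLP-1 fold changes. At 1 h 409 genes were higher and 204 lower with both agents, where independent lists would share 18.8 and 7.30 of 12664 genes. At 6 h the shared counts were 1695 and 1609 of 12587 genes, where independent lists would share 343 and 332. At neither time did limma call a gene in opposite directions. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.903 and a covariance of 0.0587 at 1 h. At 6 h these were 0.928 and 0.0931. Both responses used the same Control libraries. A set of 20 simulations of unchanged groups against those controls gave a mean correlation of 0.495 and covariance of 0.00666 at 1 h and 0.493 and 0.00684 at 6 h. The differences in covariance, 0.0520 at 1 h and 0.0863 at 6 h, estimate the shared effect. With the controls split between the responses in 6 ways, the correlation was 0.676 to 0.752 and the covariance 0.0499 to 0.0531 at 1 h. At 6 h they were 0.781 to 0.834 and 0.0847 to 0.0880.

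**Figure D3:**
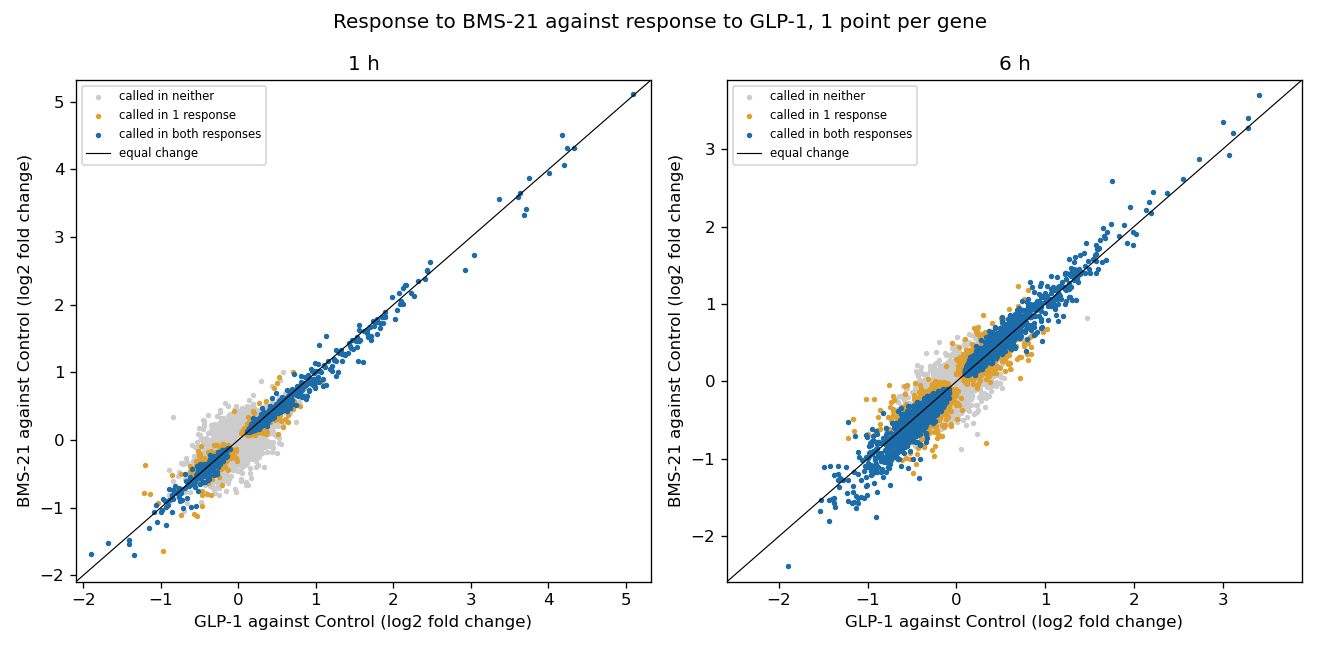
Log2 fold change with BMS-21 against log2 fold change with GLP-1, each relative to Control, at 1 h and 6 h, with 1 point per gene in grey (past the threshold in neither response), orange (in 1) or blue (in both) and a line of equal change. The correlation across genes was 0.903 at 1 h and 0.928 at 6 h.

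The change of each response between 1 h and 6 h was tested with edgeR's interaction term. With GLP-1 the log2 response of Nr4a1 fell by 2.95 (SE 0.09) and that of Fos by 2.35 (SE 0.20). The response of Per1 fell by 1.54 (SE 0.06), that of Crem by 0.86 (SE 0.14) and that of Irs2 by 0.36 (SE 0.06). The responses of Glp1r (0.32 ± 0.06, adjusted p = 0.000107) and Ins1 (0.22 ± 0.04, adjusted p = 0.000213) rose. With BMS-21 the changes were -2.92 ± 0.08 for Nr4a1, -2.23 ± 0.20 for Fos, and -1.60 ± 0.07 for Per1. They were -0.82 ± 0.16 for Crem, -0.31 ± 0.07 for Irs2, 0.27 ± 0.06 for Glp1r, 0.21 ± 0.06 for Ins1 and 0.82 ± 0.21 for Pde4b. The change of Pde4b with GLP-1 (0.49 ± 0.21, adjusted p = 0.104, 0.0430 with the replicate block and 0.0497 without Control 1h replicate 3) did not pass. Nor did those of Ins2 (adjusted p = 0.977 with GLP-1 and 0.733 with BMS-21) and Pdx1 (0.471 and 0.257).

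By list, the members whose response was higher and lower at 6 h were counted over all genes and, in brackets, adjusted over the list alone. With GLP-1 they were 2 and 16 (3 and 16) of 23 immediate early factors, 6 and 9 (7 and 10) of 23 CREB targets, 9 and 3 (11 and 3) of 14 MAPK phosphatase genes, 8 and 5 (9 and 6) of 22 beta-cell genes and 9 and 1 (10 and 2) of 21 granule genes. They were 11 and 1 (12 and 1) of 20 stress response genes, 1 and 1 (1 and 1) of 12 apoptosis genes, 2 and 7 (2 and 7) of 25 cell cycle genes, 4 and 1 (4 and 1) of 14 glycolysis genes and 0 and 14 (0 and 15) of 21 cholesterol and fatty acid genes. The rest had 2 and 7 (4 and 7) of 13 clock genes, 1 and 3 (1 and 4) of 18 insulin and IGF genes, 4 and 4 (5 and 5) of 23 adenylyl cyclase and PKA genes and 0 and 1 (0 and 2) of 4 other-cell markers. With BMS-21 they were 5 and 15 (5 and 16) of 23 immediate early factors, 6 and 10 (8 and 10) of 23 CREB targets, 11 and 3 (11 and 3) of 14 MAPK phosphatase genes, 8 and 5 (8 and 5) of 22 beta-cell genes and 10 and 1 (10 and 1) of 21 granule genes. They were 12 and 1 (15 and 1) of 20 stress response genes, 1 and 1 (1 and 1) of 12 apoptosis genes, 2 and 7 (2 and 7) of 25 cell cycle genes, 6 and 0 (6 and 1) of 14 glycolysis genes and 0 and 13 (0 and 14) of 21 cholesterol and fatty acid genes. The rest had 4 and 7 (4 and 7) of 13 clock genes, 1 and 2 (1 and 2) of 18 insulin and IGF genes, 3 and 4 (4 and 4) of 23 adenylyl cyclase and PKA genes and 0 and 1 (0 and 1) of 4 other-cell markers. In all, edgeR found the response to GLP-1 higher at 6 h than at 1 h for 1161 genes and lower for 1180 of 12976. The response to BMS-21 was higher for 1415 and lower for 1322 of 12985. Of the genes called at both times with GLP-1, 320 were higher and 115 lower at both, 37 turned from higher to lower and 15 from lower to higher. Independent lists would share 84.1, 48.1, 81.5 and 49.7 of 12507 genes. With BMS-21 these counts were 265, 119, 29 and 22. There, independent lists would share 74.2, 51.1, 75.04 and 50.5 of 12493.

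Control cells changed over the same interval, with no comparison group that kept the earlier glucose, so time, medium change and glucose are not separated here. The largest decreases from 1 h to 6 h were in Inhbe (ENSRNOG00000007601), an activin subunit gene (from 225 ± 34.3 to 2.15 ± 1.38 normalised counts, the latter under the floor of 3 reads, so that the size is uncertain, adjusted p = 1.59e-17 by edgeR), and the cystine transporter gene Slc7a11 (-4.47 ± 0.13). Decreases in the stress-induced pseudokinase gene Trib3 (-3.92 ± 0.17), Akna (-3.82 ± 0.11), Casp4 (-3.79 ± 0.19), Stk32a (-3.67 ± 0.09), Fut1 (-3.42 ± 0.14) and Abcb1a (-3.38 ± 0.18) came next. The largest increases were in Adamts8 (2.69 ± 0.28), Tgfb2 (1.89 ± 0.26) and the cholesterol synthesis gene Hmgcs1 (3.51-fold, from 714 ± 19.3 to 2516 ± 253 normalised counts, 1.81 ± 0.06). Galnt9 (1.79 ± 0.05), Mmp17 (1.69 ± 0.15), Olfml1 (1.68 ± 0.10), Derl3 (1.68 ± 0.10) and Dock5 (1.67 ± 0.09) followed them. Brackets again hold the counts adjusted over the list alone. In cholesterol and fatty acid synthesis 19 of 21 rose and 1 fell (19 and 1). Fdft1 (2.38-fold) was higher. Of the cell cycle genes 19 of 25 rose and 5 fell (19 and 5). Top2a (0.76 ± 0.03), Mki67 (0.70 ± 0.04) and Aurkb (0.85 ± 0.05) were higher. In glycolysis and glucose uptake 10 of 14 rose and 1 fell (11 and 1). Gpi (0.96 ± 0.04), Pfkp (0.96 ± 0.05) and Aldoa (0.70 ± 0.04) were higher. The stress response list had 10 of 20 members higher and 8 lower (10 and 8). The amino acid response genes Sesn2 (-1.66 ± 0.04), Asns (-1.55 ± 0.04) and Atf4 (-0.89 ± 0.04) were lower.

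The other lists were counted likewise. Immediate early factors gave 1 of 23 members higher and 17 lower (1 and 17). Nr4a1 (-1.64 ± 0.07), Jun (-1.34 ± 0.10), Atf3 (-2.33 ± 0.11) and Fos (-0.93 ± 0.15) were lower. For MAPK phosphatases and Sprouty genes 0 of 14 rose and 10 fell (0 and 11). Dusp8 (-0.61 ± 0.04), Spry1 (-1.23 ± 0.12) and Dusp4 (-1.52 ± 0.11) were lower. Of the CREB targets 5 of 22 rose and 13 fell (7 and 13). Creb3l1 (-1.99 ± 0.08), Pde10a (-0.74 ± 0.04), Per1 (-0.62 ± 0.05), Irs2 (-0.25 ± 0.04) and Crem (-0.20 ± 0.05, with adjusted p = 0.199 in 1 fit of all 24 libraries) were lower. The granule list had 2 of 21 members higher and 14 lower (2 and 16). Rab3a (-0.71 ± 0.04) and Cplx2 (-0.66 ± 0.04) were lower. Beta-cell identity and glucose sensing had 4 of 22 members higher and 11 lower (4 and 11). Glp1r (-0.51 ± 0.04), Abcc8 (-0.35 ± 0.04), Gipr (-0.32 ± 0.03) and Ins1 (-0.10 ± 0.03, adjusted p = 0.00953, 0.0509 without Control 6h replicate 4) were lower, Pdx1 was higher (0.21 ± 0.05) and Ins2 was not past the threshold (-0.09 ± 0.06, adjusted p = 0.247). The clock list had 2 of 13 members higher and 10 lower (2 and 10). Dbp (-0.84 ± 0.05), Nr1d2 (-0.71 ± 0.05) and Per2 (-1.17 ± 0.08) were lower. In apoptosis and survival 6 of 12 rose and 5 fell (6 and 5). Bbc3 was lower (-1.02 ± 0.08) and Birc5 (1.02 ± 0.08) and Bcl2l1 (0.33 ± 0.04) were higher. For insulin and IGF signalling 5 of 18 rose and 9 fell (5 and 9). Igf1r was lower (-1.05 ± 0.05) and Igfbp3 (0.69 ± 0.05) and Igfbp5 (0.81 ± 0.08) were higher. Of adenylyl cyclase and PKA genes 2 of 23 rose and 6 fell (2 and 6). Prkar2b was higher (0.78 ± 0.05) and Grk5 (-0.74 ± 0.07) and Adrbk1 (-0.29 ± 0.04) were lower. Other-cell markers gave 0 of 4 members higher and 0 lower (0 and 0) by edgeR. Pde4b did not pass (0.35 ± 0.16, adjusted p = 0.0722, 0.0320 with the replicate block and 0.0321 to 0.0344 without Control 1h replicate 1 or 2 or Control 6h replicate 2). By edgeR 3403 genes were higher and 3467 lower at 6 h of 12729 tested, 144 and 385 of them by at least 2-fold.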

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

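The tests of the replicate numbers were chosen only after the separation had been seen. The predictions for the blocked comparison, the shared controls and the other splits were written before their tests.

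A first pattern was that libraries of replicates 1 and 2 stood apart from those of replicates 3 and 4 in all 6 groups, with 3804 of 12693 genes different between these pairs within groups. Read depth as the whole cause is argued against, since the totals of these pairs were apart, with no overlap, in 1 of 6 groups (permutation p within groups 0.665). So are a few abundant genes, as removing the 10 most abundant left 3736. The labels give no date, lane or culture for the numbers, so a batch of cells, RNA handling or sequencing stays open. No biological explanation was tested, since the design names none.

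A second pattern was that BMS-21 and GLP-1 at 6 h differed in 217 genes by limma once the replicate number was a block, against 2 without it. DESeq2 with the block gave 38, and 5 genes were called in replicates 1 and 2 and again in 3 and 4. A blocked fit that calls genes in any split is argued against, as the 7 other assignments within pairs gave 0. They are too few to exclude chance. Of the 217 genes, 85.7% lay farther from Control with BMS-21 than with GLP-1, which may reflect a larger response of the same genes to BMS-21. This is a hypothesis, and the doses were not matched, so the compound and its dose were not separated. The median size of the blocked differences was 0.18 on the log2 scale.

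The last pattern weighed was that the responses to BMS-21 and GLP-1 moved together across genes. Shared control libraries as the whole source are argued against at 1 h, where the lowest covariance with the controls split was 0.0499 and the highest simulated one 0.00709, and at 6 h, where these values were 0.0847 and 0.00719. That both agents act on the same transcripts in these cells is a hypothesis consistent with these values. A change common to all treated wells but not to Control wells stays open and was not tested.

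Other splits of the 8 libraries of a comparison into 4 and 4 were compared with the real one. For the number of genes, 1 of 35 splits, the real one, gave a count as large with GLP-1 at 1 h (837, highest other 486) and GLP-1 at 6 h (4011, highest other 21). The same held for BMS-21 at 1 h (751, highest other 624) and BMS-21 at 6 h (4253, highest other 7). For Control at 6 h against 1 h it was also 1 of 35 (6870, highest other 0). For BMS-21 against GLP-1 at 1 h the splits decide nothing, since 35 of 35 reach a real count of 0 (highest other 1455). At 6 h chance is not excluded (4 of 35, 2 genes, highest other 1186). In the comparisons of 2 groups the split with the highest other count was that of replicates 1 and 2 against 3 and 4, which points to a structure of the samples. Blocked counts at 1 h and 6 h were 1513 and 5331 for GLP-1 and 1551 and 5008 for BMS-21. The direct comparison gave 85 and 217. Given the pairing, the 8 splits that part all 4 pairs apply, too few to exclude chance. Their highest other was 1 with the block, for BMS-21 at 1 h, and 0 otherwise.

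For lists past the threshold, the real split alone ranked first with GLP-1 at 1 h (1 of 35 splits, 9 lists, highest other 6). The same held for GLP-1 at 6 h (1 of 35, 9 lists, highest other 8). It also held for BMS-21 against GLP-1 at 6 h (1 of 35, 6 lists, highest other 5). An estimated correlation left 5, 4 and 0 lists, and leaving out 1 library left as few as 7, 8 and 1. These ranks are weak and do not exclude chance. Chance is not excluded with BMS-21 at 1 h (2 of 35, 6 lists, highest other 6), BMS-21 at 6 h (2 of 35, 9 lists, highest other 9) and BMS-21 against GLP-1 at 1 h (20 of 35, 2 lists, highest other 6). For the change of a response with time, 2 of 100 splits gave as many genes for GLP-1 (2341, highest other 2411) and 3 of 100 for BMS-21 (2737, highest other 3140). The other splits with as many genes kept the 6 h groups whole, and with neither time whole the highest was 1 and 0. As the splits break the response too, they cannot decide on chance for the change, which rests on the tests of genes.

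The test of the difference between time points singled out those 2341 genes with GLP-1 and 2737 with BMS-21, and, over both agents, 15 results of named genes. With GLP-1 the log2 response changed from 1 h to 6 h by -2.95 for Nr4a1, -2.35 for Fos, -1.54 for Per1, -0.86 for Crem, -0.36 for Irs2, 0.32 for Glp1r and 0.22 for Ins1. With BMS-21 it changed by -2.92 for Nr4a1, -2.23 for Fos, -1.60 for Per1, -0.82 for Crem, -0.31 for Irs2, 0.27 for Glp1r, 0.21 for Ins1 and 0.82 for Pde4b. The test between the agents at 6 h singled out Ccny (0.24) and Hspa12a (-0.34).

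Single libraries far from the other 3 of their group were sought with Dixon's ratio, the gap to the nearest library over the range of the group against its critical value for 4 libraries, for 146 named genes in 6 groups. Of 876 such tests 43 exceeded it, where chance gives about 1 in 20, or 43.8. In Control 1h the ratio exceeded it for Ccny (0.962, highest) for replicate 1, Pik3r1 (0.930, lowest) and Klf4 (0.839, lowest) for replicate 2 and Ins2 (0.962, highest), Igf1r (0.962, highest), Zfp189 (0.856, lowest) and Nkx2-2 (0.850, highest) for replicate 3. In GLP-1 1h the ratio exceeded it for Bcl2l11 (0.929, highest), Fosb (0.913, highest), Calr (0.909, lowest) and Cplx2 (0.830, lowest) for replicate 2, Dusp8 (0.942, highest), Klf6 (0.935, highest), Neurod1 (0.875, highest) and Camk4 (0.861, lowest) for replicate 3 and Adrbk1 (0.863, highest) for replicate 4. In BMS-21 1h the ratio exceeded it for Prkacb (0.901, highest), Grk5 (0.870, highest) and Per2 (0.843, lowest) for replicate 2, Klf6 (0.911, highest) and Fut1 (0.902, highest) for replicate 3 and Insig1 (0.902, highest) and Bhlhe40 (0.831, lowest) for replicate 4. In Control 6h the ratio exceeded it for Dusp4 (0.937, lowest) for replicate 1, Per2 (0.857, lowest) for replicate 2, Mylk (0.950, lowest) and Junb (0.934, highest) for replicate 3 and Pcna (0.937, highest) for replicate 4. In GLP-1 6h the ratio exceeded it for Zfp189 (0.980, highest) and Acaca (0.883, highest) for replicate 2, Dusp6 (0.916, highest), Spry4 (0.905, highest) and Sesn2 (0.830, highest) for replicate 3 and Ccnd3 (0.906, highest) and Irs2 (0.832, highest) for replicate 4. In BMS-21 6h the ratio exceeded it for Pdx1 (0.868, highest) and Fut1 (0.865, highest) for replicate 1, Grk5 (0.872, highest) for replicate 2 and Abcc8 (0.899, highest), Camk4 (0.869, highest), Junb (0.862, highest), Pax6 (0.857, highest) and Dusp6 (0.841, highest) for replicate 3.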

How the results depend on the processing

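The edgeR test on the recovered reads, edgeR and DESeq2 with the block, scaling by library totals, the estimated correlation with the block and the tests within replicates 1 and 2 or 3 and 4 were chosen only after the results had been seen. Total counts of genes past the threshold stayed within 1.5 times the reported value unless given here. The cause was not tested except where the construction of an alternative shows it, as with fewer libraries or a stricter criterion.

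With the replicate block 1513 genes passed for GLP-1 at 1 h (837 without it), 1551 for BMS-21 at 1 h (751), 85 for BMS-21 against GLP-1 at 1 h (0) and 217 at 6 h (2). With edgeR and the block these counts were 1542, 1567, 86 and 226. DESeq2 with the block gave 2 genes for BMS-21 against GLP-1 at 1 h and 38 at 6 h. At 6 h that comparison gave 18 genes with DESeq2 without a block, 14 with all 24 libraries in 1 fit, 1 with a mean of at least 50 (where the adjusted p of Hspa12a was 0.0509) and 0 with a fold of at least 1.5 by limma. Replicates 1 and 2 alone gave 37 there and replicates 3 and 4 alone 39. For GLP-1 at 1 h replicates 3 and 4 alone gave 556 genes and for BMS-21 at 1 h 495. A fold of at least 1.5 besides the threshold left 262 genes for GLP-1 at 1 h, 684 for GLP-1 at 6 h, 253 for BMS-21 at 1 h, and 792 for BMS-21 at 6 h. Some counts of lower genes moved farther than the totals. They went from 307 to 506 for GLP-1 at 1 h and from 1967 to 2960 at 6 h with scaling by library totals. DESeq2 gave 201 for GLP-1 at 1 h, and with the block 140, 1194 at 6 h and 169 and 1360 for BMS-21. The fold criterion left 607 and 734 for the changes of the GLP-1 and BMS-21 responses with time and 1678 for Control at 6 h against 1 h.

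Of the lists past the threshold, the estimated correlation left 5 of 9 for GLP-1 at 1 h, 4 of 9 at 6 h, 2 of 6 for BMS-21 at 1 h and 4 of 9 at 6 h. It left 1 of 2 for BMS-21 against GLP-1 at 1 h and 0 of 6 at 6 h by camera. With the block as well it left 3, 4, 2, 3, 0 and 0. Scaling by library totals gave 5 lists for GLP-1 at 1 h. For BMS-21 against GLP-1 at 1 h the block gave 6 lists, edgeR with the block 6, DESeq2 with the block 7 and replicates 1 and 2 alone 1. At 6 h all 24 libraries in 1 fit gave 3, DESeq2 with the block 10, replicates 1 and 2 alone 2 and replicates 3 and 4 alone 10. With the limma block the lists that changed sides were apoptosis for BMS-21 at 1 h, the CREB, beta-cell, stress response and glycolysis lists for BMS-21 against GLP-1 at 1 h and the beta-cell list at 6 h. The named genes that changed sides were Ins1 and Ins2 for BMS-21 against GLP-1 at 1 h and Pde4b in the change of the GLP-1 response and in Control over time.

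Leaving out each library in turn gave 670 to 841 genes for GLP-1 at 1 h, 3509 to 3749 at 6 h, 597 to 758 for BMS-21 at 1 h, and 3671 to 4139 at 6 h. It gave 0 to 0 for BMS-21 against GLP-1 at both times by limma, 2021 to 2287 and 2376 to 2744 for the changes of the GLP-1 and BMS-21 responses and 6485 to 6588 for Control over time. The lists past the threshold numbered 7 to 8, 8 to 9, 5 to 7 and 9 to 10 in the comparisons with Control in the same order. For BMS-21 against GLP-1 they numbered 2 to 5 at 1 h, with 5 without GLP-1 1h replicate 3 or BMS-21 1h replicate 1, and 1 to 7 at 6 h, with 1 without BMS-21 6h replicate 3 and 2 without GLP-1 6h replicate 2.

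Among named genes under all alternatives, 50 tests ended a call and 1214 did not for GLP-1 at 1 h, and 23 ended one and 1 made one for GLP-1 at 6 h with 1425 the same. For BMS-21, 49 ended one and 1100 did not at 1 h, and 35 ended one at 6 h with 1413 the same. The only reversal was Ins2 with BMS-21 at 6 h, which was -0.15 in replicates 1 and 2 alone (adjusted p = 7.29e-05) and 0.32 in replicates 3 and 4 (0.289), against a reported value of 0.09. For BMS-21 against GLP-1, 4 tests made a call at 1 h and 19 ended one at 6 h. In the changes of the responses 3 tests ended a call for each agent and 2 made one for GLP-1, and in Control over time 11 ended one and 4 made one. DESeq2 with the block ended the calls of Bcl2l11 (adjusted p = 0.0865), Irs1 (0.0789) and Pde4b (0.108) for GLP-1 at 1 h. It also ended those of Prkacb (0.0672) and Sox9 (0.148) for BMS-21 at 1 h and of Gcg (0.0625) and Pdx1 (0.0631) for BMS-21 at 6 h.

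A fold criterion does not apply to list tests, and using the authors' scaling with none further is the reported setting itself. For the results over time the pseudocounts were run with limma. A gene under 3 reads in a library, 0.228 to 0.281 RPM, was below the floor of detection. The smallest fold simulated was recovered in 44.0 to 72.0% of genes by limma and 42.0 to 75.5% by edgeR.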

Other observations

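The lists and genes that differ between replicate numbers were examined only after the separation of replicates 1 and 2 from 3 and 4 had been seen. The genes named here from the blocked comparison were likewise chosen after their values were seen, whereas the response score was planned beforehand.

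With the replicate number as a block, the genes below were among those that differed between BMS-21 and GLP-1 at 6 h. Txnip, which fell less from Control with BMS-21, was higher (log2 difference 0.21 ± 0.02), as was Slc2a1, which encodes a glucose transporter (0.24 ± 0.04). The adenylate kinase gene Ak4 (0.26 ± 0.04), Camk4 (0.24 ± 0.04) and the granule gene Scg2 (0.14 ± 0.02) were higher too. Trib3 (0.37 ± 0.06), Herpud1 (0.28 ± 0.04) and the chaperone gene Hspa5 (0.11 ± 0.02) were higher with BMS-21. Lower with BMS-21 were the calcium channel gene Cacna1a (-0.25 ± 0.04), Acaca (-0.20 ± 0.03), the pyruvate kinase gene Pklr (-0.18 ± 0.03) and Gcgr (-0.18 ± 0.03).

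Within groups, the list of the unfolded protein response and integrated stress response was higher in replicates 3 and 4 than in 1 and 2, with 18 of 20 members higher and 0 lower (median log2 difference 0.19, camera adjusted p = 1.57e-17, and adjusted p = 0.0386 with an estimated correlation). Chac1 (0.52 ± 0.14), Trib3 (0.47 ± 0.08), Ddit3, which encodes the transcription factor CHOP (0.41 ± 0.05), Herpud1 (0.38 ± 0.06), Dnajb9 (0.36 ± 0.03), Creld2 (0.31 ± 0.02) and Hspa5 (0.23 ± 0.02) were higher there. The cell cycle list (5 of 25 higher, 12 lower, camera adjusted p = 0.0126, but adjusted p = 0.568 with an estimated correlation) was lower, and so was the glycolysis list (1 of 14 higher, 6 lower, camera adjusted p = 0.0359, but adjusted p = 0.568 with an estimated correlation).

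The hypothesis that the response to BMS-21 was larger as a whole was tested with a score per library, the mean signed log2 change against Control over the genes called for the mean of both agents. At 1 h (1066 genes) the score was 0.523 ± 0.0225 (SD, n = 4) with GLP-1 and 0.511 ± 0.0348 with BMS-21 (exact two-sided permutation p = 0.686). It was higher with BMS-21 in 1 of 4 pairs of replicate numbers. At 6 h (4845 genes) it was 0.349 ± 0.0111 with GLP-1 and 0.377 ± 0.0269 with BMS-21 (exact two-sided permutation p = 0.171, adjusted 0.343 over both times). It was higher with BMS-21 in 4 of 4 pairs, where the exact two-sided sign-flip test gave 0.125, the smallest p that 4 pairs allow. The score therefore left the hypothesis undecided at both times.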
